A study of Rattus norvegicus with 8 samples.

How the data were processed

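The series measured one rat RNA, a control mix named for brain, heart and liver, against itself on 8 spotted arrays with 2 dyes. Per the labels, total RNA was extracted with a phenol-based reagent and labelled indirectly, and each array received the same RNA in the Cy3 and the Cy5 channel under the names test and ref. The labels put the test RNA in Cy5 on 4 arrays, called test_in_Cy5 here, and in Cy3 on the other 4, called test_in_Cy3, and number the arrays of each orientation 1 to 4. The arrays were technical replicates of 1 biological sample, so every p-value below measures technical spread only.

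The deposited scanner tables give, per spot, an intensity and a local background intensity in each channel, the standard deviation of the background and a flag of 0 or 1. Per the file headers the intensities were not background-subtracted. They reached a ceiling of 5242800, which is 80 times the 16-bit maximum of 65535, so a spot value was read as a sum over 80 pixels. The scanner and its software are not given in the sources used here, and the meaning of the other deposited column, the flag, is not stated. Channel 1 was taken as Cy3 and channel 2 as Cy5 from the labels, and the spots named cy3 had the higher values in channel 1. The authors' own values, 1 per clone spot and array, are deposited without a stated scale, centring or direction. Per array, they correlated at 0.583 to 0.824 with the background-subtracted log2 ratio of test over ref after loess per array. Their direction was therefore taken as test over ref. Their column medians lay between 7.11e-15 and 0.003043. Their log base was taken as log2 because their spread was 0.9245 to 1.009 times that of the background-subtracted log2 ratio after loess per print block, and the method that made them is not given in the sources used here. They served as an alternative.

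Each array held 18240 spots in 48 print blocks of 380, of which 644 were control spots, 56 of them blanks, and 17596 carried 8778 rat cDNA clones. Of these clones, 8758 were spotted 2 times and 20 were spotted 4 times. The files name clones by library identifiers and do not pair them with genes. None of the identifiers matched a symbol or synonym in the table of 47357 rat genes, so 0 clones have a gene name here. The 11 marker lists and 6 gene families chosen in advance could not be scored, and marker detection and the shift of gene lists were not analysed here.

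Intensities were corrected with the normexp method at an offset of 50 on the deposited scale. Log2 ratios of Cy5 over Cy3 were normalised within each array by loess with a span of 0.3 and 4 iterations, with control spots at weight 0, and the spots of a clone were averaged. A linear model was fitted per clone with limma 3.58.1 in R 4.3.3, with 1 coefficient for the dye effect, the mean log2 Cy5/Cy3 over both orientations, and 1 for test over ref, which is the swap-corrected ratio: the log2 Cy5/Cy3 of test_in_Cy5 minus that of test_in_Cy3, divided by 2. Moderated statistics had 6 residual and 1.84 prior degrees of freedom. A clone was called at a Benjamini-Hochberg adjusted p under 0.05 over 8778 clones. Unswapped analyses fitted the mean log2 Cy5/Cy3 of the 4 arrays of 1 orientation. Agreement, sizes of log ratios, intensity dependence and spread are values without a test, and correlations across clones are descriptive because clones are not independent replicates. Brightness was divided into 5 equal bins of mean log2 intensity. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

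On simulated data with the measured residual spread of 8778 clones, the dye comparison recovered 67% of 100 clones changed by 0.5 log2 units and 85% of 100 changed by 1, with 8 false calls among 160. For test over ref the shares were 59% and 85%, with 9 false calls among 153. The simulation used independent normal errors with the same spread for a clone on all 8 arrays. On the real arrays the standard deviation of the log2 ratios ran from 0.181 to 0.646, so these shares may not carry over. For arrays, the number of arrays limits the precision. A spot was to count as above background where it exceeded the local background by more than 2 background standard deviations. All clone spots and all 56 blanks passed that rule, so it separated nothing. The 95th percentile of the blanks was therefore added as a stricter rule.

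Named clones were to be the called clones with the largest dye coefficients, of 1 sign on all 8 arrays, above local background and not saturated on every array. As they carry no gene symbols, naming was limited to 2 clones per direction, and for test over ref to the 1 clone with the smallest p, since none was called. Groups, tests, this rule and the alternatives of no or plain background subtraction, median centring, loess per print block, Aquantile scaling, a local background filter, the authors' values, the spot flag, a log2 limit, the label number as a block, array weights, ordinary least squares and leaving out each array were fixed before the data were examined. Intensities divided by 80 before normexp, the blank filter and the omission of both arrays numbered 4 were chosen after the data were seen. No pair of arrays held identical values.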

Results

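The series asked how far the dyes alone shift the log ratios of a 2-colour array when both channels hold the same rat RNA. In 4 arrays the RNA named test was labelled with Cy5 and in 4 with Cy3, the RNA named ref taking the other dye, and each array measured 8778 cDNA clones. Apart from test_in_Cy3 replicate 3, the median clone intensity lay between 102852 and 117734 in Cy3 and between 163258 and 221545 in Cy5. The 56 blank spots had medians of 91905 to 101562 in Cy3 and 109208 to 134132 in Cy5. Of the clones, 950 (10.8%) exceeded the 95th percentile of the blanks in both channels on all 8 arrays, 2121 (24.2%) did so on at least 4 arrays, and 5752 (65.5%) on none.

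Test_in_Cy3 replicate 3 was brighter than the other arrays. Its median clone intensity was 214695 in Cy3 and 603655 in Cy5, and its blanks had medians of 182686 and 447122. The Cy5 gain over the other 3 arrays of its orientation, taken over clones at or below the median brightness, ranged from 97990 to 711100 between the 48 print blocks. The flag value was 0 for 4213 of its spots, of which 4198 lay in block rows 1 to 6 and block columns 2 to 4, against 48 to 372 spots on each of the other arrays.

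**Figure D1:**
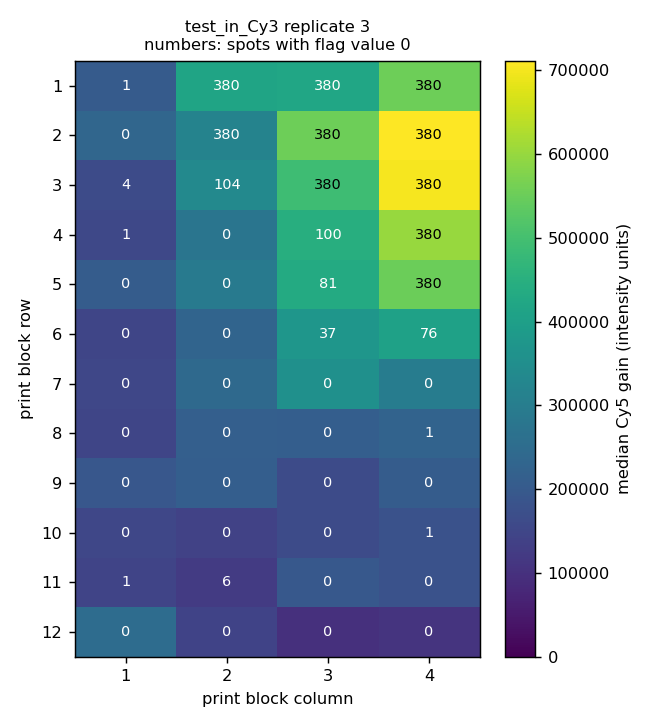
Map of the 48 print blocks of test_in_Cy3 replicate 3, with 12 block rows and 4 block columns. Colour gives the median Cy5 intensity gain, in intensity units, of clones at or below the median brightness over the mean of the other 3 arrays of the orientation, and the printed numbers count spots with a flag value of 0. The gain is highest in the upper right blocks, where it reaches 711100, and in 10 blocks all 380 spots have the flag value 0.

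Before normalisation the Cy5 channel was brighter than the Cy3 channel on every array, and the excess was larger among bright than among dim clones. The array medians of log2 Cy5/Cy3 ranged from 1.37 to 2.19. From the dimmest to the brightest of 5 bins the median log2 Cy5/Cy3 was 1.32 ± 0.32, 1.62 ± 0.21, 1.81 ± 0.22, 1.97 ± 0.26 and 2.00 ± 0.31 (SD, n = 8 arrays). The brightest bin exceeded the dimmest by 0.68 ± 0.40 (SD, n = 8), and the difference was above 0 on 8 of 8 arrays. Without background correction the difference was 1.17 ± 0.34 (SD, n = 8), again above 0 on 8 of 8 arrays.

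**Figure D2:**
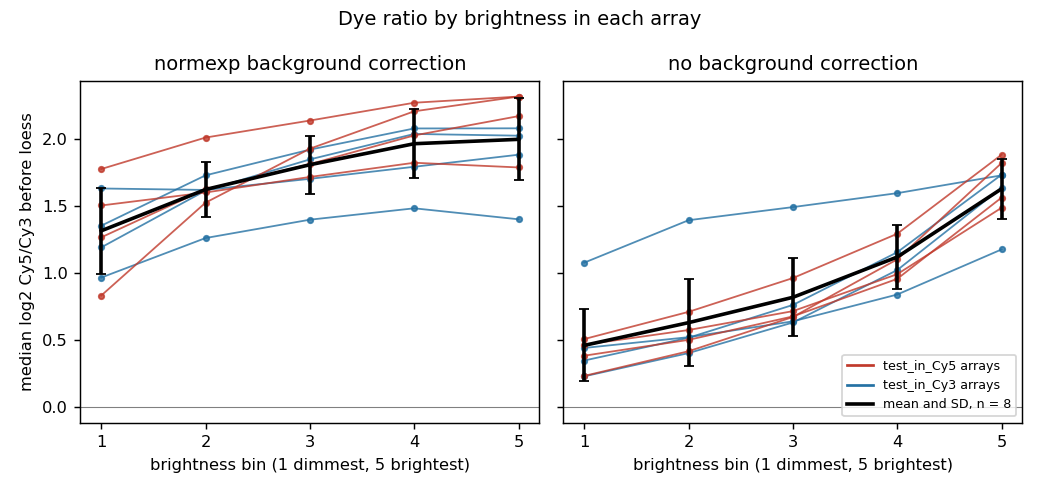
Median log2 Cy5/Cy3 before loess in 5 bins of brightness, with normexp background correction on the left and without background correction on the right. Thin lines are single arrays, coloured by orientation, and the black line gives the mean and SD over 8 arrays. With normexp the mean rises from 1.32 in bin 1 to 2.00 in bin 5, and without correction it rises from 0.46 to 1.63.

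The dye effect, the part of the log ratio that stays with the dye when the samples are swapped, was addressed with all 8 arrays. After loess, 231 of 8778 clones kept a dye effect at a limma adjusted p under 0.05. Cy5 was higher for 40 of them (17.3%) and Cy3 for 191. The median absolute effect of the called clones was 0.67 on the log2 scale, 58 exceeded 1, of which 2 had Cy5 higher, and 162 had the same sign on all 8 arrays. At an unadjusted p under 0.05 there were 2138 clones (24.4%). Of the 231, 33 exceeded the blanks on all 8 arrays and 21 had a spot at the scanner ceiling on some array, as did 22 clones in all.

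Among clones with Cy5 higher, UI-R-E1-fy-c-10-0-UI had a dye effect of 1.27 ± 0.14 (SE, limma adjusted p = 0.0084) and UI-R-C0-iw-d-08-0-UI one of 0.76 ± 0.11 (SE, limma adjusted p = 0.022). Each had Cy5 higher on 8 of 8 arrays, as the naming rule required. The size for UI-R-E1-fy-c-10-0-UI differed between orientations, with a mean log2 Cy5/Cy3 of 2.08 in test_in_Cy5 and 0.47 in test_in_Cy3. For UI-R-C0-iw-d-08-0-UI the means were 0.90 and 0.62. Among clones with Cy3 higher, UI-R-E1-fj-h-06-0-UI had a dye effect of -2.36 ± 0.42 (SE, limma adjusted p = 0.035) and UI-R-C0-gu-e-07-0-UI one of -1.93 ± 0.29 (SE, limma adjusted p = 0.023). Each had Cy3 higher on 8 of 8 arrays, again by the rule. On test_in_Cy3 replicate 3 the 4 clones, in this order, had their smallest log2 Cy5/Cy3, at 0.22, 0.07, -0.33 and -0.09. None of these 4 clones exceeded the blanks on any array. Without background correction they kept their sign with effects of 0.12, 0.10, -0.13 and -0.09, and they were called again. Log2 ratios as a whole were narrower in that setting, with a median 95th percentile over single arrays of 0.16 against 1.07. None of the 4 was called with loess per print block, where their effects were 0.47, 0.31, -1.06 and -0.62. Nor was any called, at unchanged effects, with ordinary least squares (adjusted p = 0.0509 to 0.0919). With the authors' values UI-R-E1-fj-h-06-0-UI alone was called. All but UI-R-E1-fy-c-10-0-UI lost their call without test_in_Cy3 replicate 1 and in other fits that left out 1 array.

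The number and direction of the dye calls changed with the processing. Without background correction 756 clones were called, 359 with Cy5 higher (47.5%) and 397 with Cy3 higher, at a median absolute effect of 0.10, and 175 of the 231 were called again in the same direction. Effect sizes with and without background correction are not on the same scale. Cy5 was higher for 300 of 653 called clones (45.9%) with plain background subtraction, for 1089 of 2534 (43.0%) with median centring, for 220 of 447 (49.2%) with the authors' values and for 36 of 85 (42.4%) among clones above the blanks. With loess per print block 35 clones were called, 3 with Cy5 higher, and 32 of the 35 were among the 231. Ordinary least squares called 34. Leaving out test_in_Cy5 replicates 1, 2, 3 and 4 gave 151, 60, 112 and 118 calls, of which 111, 57, 90 and 99 were among the 231 in the same direction. Leaving out test_in_Cy3 replicates 1, 2, 3 and 4 gave 31, 49, 228 and 79, of which 31, 46, 168 and 74 were.

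Test over ref compared the RNA with itself after the dye effect was taken out. No clone was called: limma called 0 of 8778 at an adjusted p under 0.05, and the smallest adjusted p was 0.215. At an unadjusted p under 0.05 there were 625 clones (7.12%), and ordinary least squares called 0, with 667 at an unadjusted p under 0.05. The clone with the smallest p, UI-R-A0-ao-e-06-0-UI, had a test over ref value of -0.98 ± 0.11 (SE, limma adjusted p = 0.22) and did not exceed the blanks on any array. Without test_in_Cy3 replicate 2, 1 clone was called. Without both arrays numbered 4, whose control spots ran against their labels, 0 were called and 578 had an unadjusted p under 0.05.

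Each orientation alone showed what the same comparison gives without a swap. In the test_in_Cy5 arrays 22 clones departed from 0 at a limma adjusted p under 0.05, 2 with Cy5 higher and 20 with Cy3 higher, with 1697 at an unadjusted p under 0.05. All 22 had the same sign in the mean of the test_in_Cy3 arrays. In the test_in_Cy3 arrays limma called 0 clones, with a smallest adjusted p of 0.558 and 758 clones at an unadjusted p under 0.05. Whether the orientations differed in number of calls was not tested. Without background correction the counts were 351 and 55, and leaving out any 1 of the 4 test_in_Cy5 arrays (replicate 1, 2, 3 or 4) left 0 calls in that orientation.

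The dye effects of both orientations, which share no array, were compared clone by clone. Across 8778 clones the mean log2 Cy5/Cy3 of test_in_Cy5 and test_in_Cy3 correlated with Pearson's r of 0.606 and Spearman's rho of 0.477, and 65.1% of clones had the same sign. Without background correction r was 0.821 and rho 0.436, and 65.2% had the same sign. The unswapped calls made without background correction shared 3 clones with Cy5 higher, against 0.266 for independent lists of those lengths, and 35 with Cy3 higher, against 0.911. Among the clones above the blanks r was 0.912. It was lower, at 0.416, with loess per print block and at 0.418 with the authors' values. Clones with a spot at the scanner ceiling had large dye effects. Without background correction the 21 of them among the dye calls had a median absolute effect of 1.57, against 0.10 for the other 210. The SD of the dye effects in that setting was 0.0994 over all clones and 0.0635 over clones without such a spot. Their part in the values of r was not tested, and neither was that of a signal trend across print blocks.

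**Figure D3:**
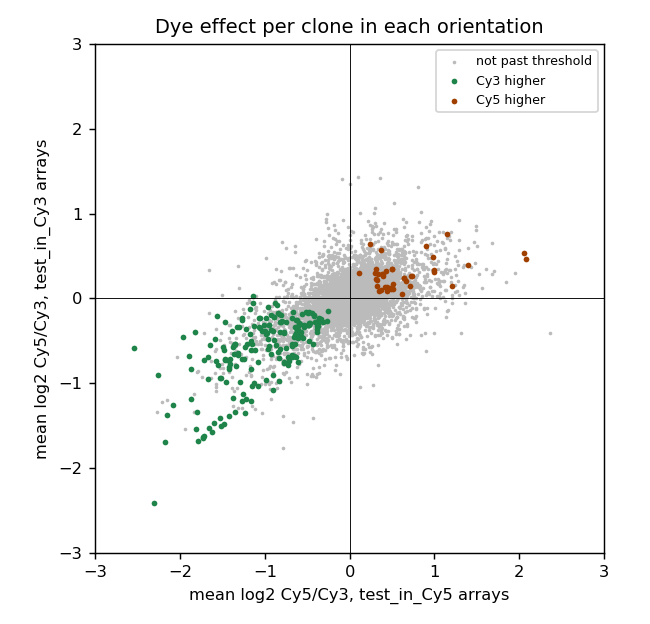
Mean log2 Cy5/Cy3 of each of the 8778 clones in the 4 test_in_Cy5 arrays (horizontal) and in the 4 test_in_Cy3 arrays (vertical), both axes in log2 units. Green points mark the 191 clones called with Cy3 higher, brown points the 40 called with Cy5 higher and grey points the rest. Called clones lie mostly in the lower left, and r over all clones is 0.606.

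Averaging narrowed the log ratios, and the swap-corrected ratios were the narrowest. In single arrays a median of 5.68% of clones had an absolute log2 ratio over 1, with a range of 0.262% to 10.9% over 8 arrays. For means of 2 arrays of the same orientation the median share was 3.67% (0.615% to 6.64% over 12 pairs), and for swap-corrected ratios of 2 arrays of opposite orientation it was 1.29% (0.763% to 2.19% over 16 pairs). The pairs share arrays, so the ranges describe these arrays and were not tested. The 95th percentile of the absolute log2 ratio had medians of 1.07, 0.87 and 0.62. Without background correction the shares were 0.308%, 0.262% and 0%, and the 95th percentiles 0.16, 0.14 and 0.10.

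**Figure D4:**
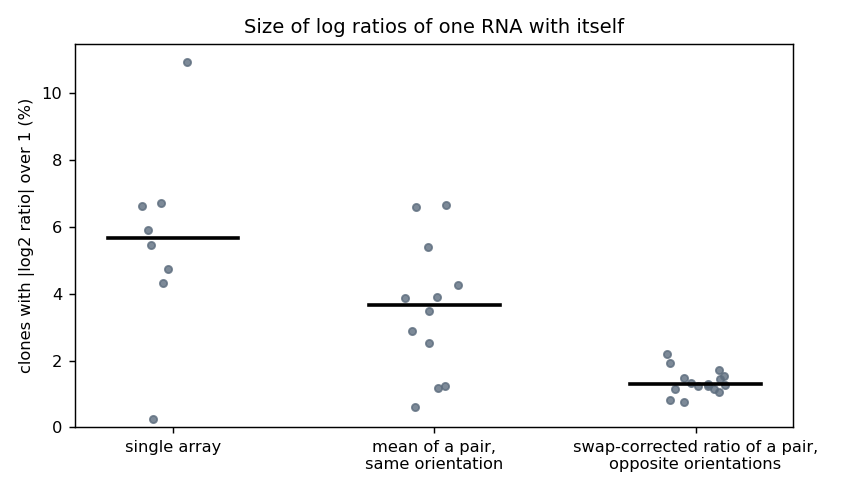
Percentage of clones with an absolute log2 ratio over 1, in log ratios of 1 RNA with itself. Points are 8 single arrays, 12 pairs averaged within an orientation and 16 swap-corrected pairs, and bars are medians of 5.68%, 3.67% and 1.29%. The lowest single array, at 0.262%, is test_in_Cy3 replicate 3.

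With normexp correction the technical spread was smaller for brighter clones, and without background correction it was not. The residual standard deviation of a clone over the 8 arrays had a median of 0.25 log2 units and a 95th percentile of 0.82. From the dimmest to the brightest bin its median was 0.59, 0.38, 0.25, 0.16 and 0.10. Without background correction the median was 0.067 over all clones, 0.063 in the dimmest bin and 0.072 in the brightest. Within arrays, duplicate spots of a clone had a median absolute difference, divided by the square root of 2, of 0.15 ± 0.036 log2 units (SD, n = 8 arrays), and of 0.043 ± 0.0025 without background correction (SD, n = 8). The log2 ratios themselves were narrower without background correction, with a median 95th percentile over single arrays of 0.16 against 1.07. A smaller spread in that setting therefore does not by itself mean higher precision.

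The 18 numbered sets of control spots, whose content is not given in the sources used here, were compared in the same way. Over label numbers 1 to 3 the swap-corrected log2 ratio of test over ref was 3.00 ± 0.069 for control-15, 1.45 ± 0.062 for control-11, -1.75 ± 0.0065 for control-16 and -1.44 ± 0.016 for control-12 (SD, n = 3). Of the spots of control-11, control-16 and control-12, 19.3%, 11.4% and 5.68% were at the scanner ceiling in Cy5. For the arrays labelled number 4 the values were -2.77, -1.49, 1.64 and 1.42. The blanks had a value of -0.04 over numbers 1 to 3. Across the 18 sets the values of numbers 1 to 3 correlated at 0.995 to 0.998 with each other and at -0.985 to -0.975 with number 4. Several of the 18 sets were mostly at the ceiling in Cy5, up to 100% of spots for control-3 and control-4, which limits their ratios.

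**Figure D5:**
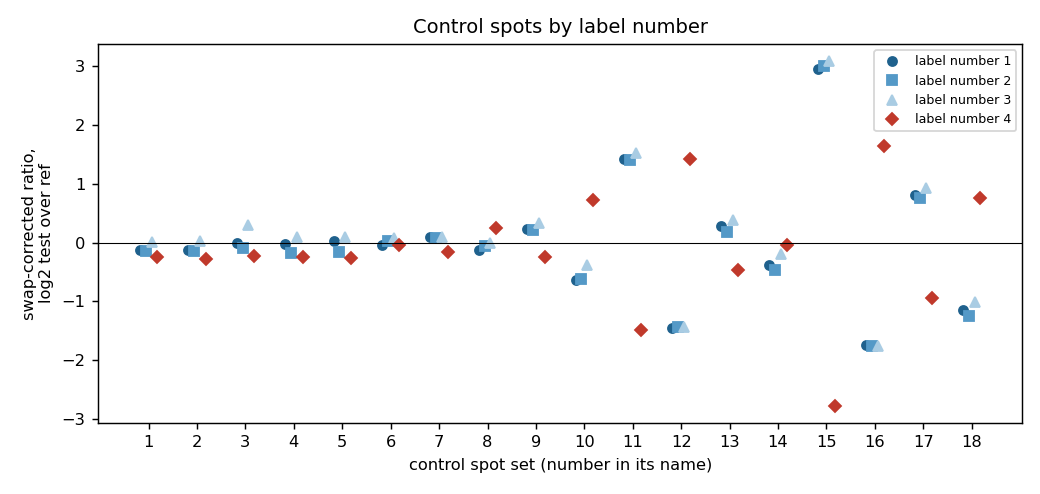
Swap-corrected log2 ratio of test over ref for each of the 18 numbered sets of control spots, with 1 symbol per label number, each from 1 array of either orientation. Numbers 1 to 3 lie together, at a mean of 3.00 for control-15 and -1.75 for control-16. The arrays labelled number 4 lie on the opposite side of 0 for these sets, at -2.77 and 1.64.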

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

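The tests of print blocks, of background correction, of the saturated clones taken alone, of the number 4 control spots, of print block gains and of Cy3 on the bright array were chosen after the result was seen. The scanner gain and added signal on test_in_Cy3 replicate 3, the saturated share of all dye calls and the counts over regrouped arrays were chosen before their results were seen.

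The control spots stood outside every comparison of clones, and 5 of their 18 numbered sets gave test over ref values over 1 in size where the blanks gave -0.04. Over numbers 1 to 3 the means were 3.00 for control-15, 1.45 for control-11, -1.75 for control-16, -1.44 for control-12 and -1.14 for control-18. The arrays labelled number 4 gave -2.77, -1.49, 1.64, 1.42 and 0.76. Spots at the scanner ceiling in Cy5 made up 0% for control-15, 19.3% for control-11, 11.4% for control-16, 5.68% for control-12 and 65.9% for control-18, which had 30.7% in Cy3 as well.

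The reversal at number 4 argues against 1 mislabelled array, since all 5 of these control sets were reversed on both arrays of that number. An exchange of both arrays between the orientations may account for it, as the reversed values had 0.923 to 1.03 times the size of those of numbers 1 to 3 in 4 of the sets, and 0.67 times in control-18, whose spots were mostly saturated in Cy5. An exchange of the control RNA between the test and ref samples of number 4 predicts the same values, up to the same 1.03, and cannot be told apart from it because both samples hold the same rat RNA. No biological explanation was tested, as the design has 1 sample. The labels were kept as given in every comparison.

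Test_in_Cy3 replicate 3 lay far from the other 3 arrays of its orientation in 6 measures. Its median intensities were 214695 (Cy3) and 603655 (Cy5), its blank medians 182686 and 447122, its spots with a flag value of 0 numbered 4213, and the standard deviation of its log2 ratios was 0.181 against 0.448 to 0.498. Outside these 6 measures, its median local background in Cy5 was 18260 against 11839.5 to 12541. Its median log2 Cy5/Cy3 without background correction or loess was 1.49 against 0.649 to 0.790. Test_in_Cy5 replicate 3 had 372 spots with a flag value of 0 against 48 to 95. Of 26 groups of 4 values tested, chance would mark about 5%, and the measures of 1 array are not independent.

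The tables argue against a higher scanner gain on this array, because its Cy5 factor over the other 3 arrays was 3.38 times as high at blanks as in clones above the 90th percentile of brightness, where it was 0.990. They argue against an equal addition to every spot as well, given the print blocks, whose highest median gain was 7.26 times the lowest (bootstrap 95% interval 5.75 to 12.2). The planned comparison alone, a gain of clones below the 10th percentile of brightness at 0.54 times that of the blanks, had an interval of 0.379 to 0.920 and leaves this open. With 1 such bright array, neither interval measures spread between arrays. All 56 blanks lay in block columns 2 and 4, and the highest block gain was in column 4. Their position may therefore enter each comparison that uses the blanks. Added Cy5 signal in one region is argued against by the other channel, whose blanks were 1.83 times as bright as on the other arrays. Gains above 0 in all 48 blocks in both channels, for clones at or below the median brightness, argue against it as well. Clones above the 90th percentile of brightness showed no such gain. Their Cy5 gain was -12790, against 305500 at the blanks, and their Cy3 factor was 0.906. Uneven added signal over the whole array in both channels, limited to the dimmer spots, stays open and was not tested. Neither was a biological explanation.

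Chance is argued against for the count of dye calls, but single clones were not tested this way. Of 100 drawn sign patterns of the 8 arrays, 1, the real one, gave as many as 231, and the highest other gave 28. For unswapped test_in_Cy5 the 8 sign patterns are too few, with 1 giving as many as 22 and the highest other 0. For test over ref and unswapped test_in_Cy3 the real count was 0, which 35 of 35 splits and 8 of 8 sign patterns reach by construction, so these counts decide nothing. The highest others were 1 and 0.

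The dye calls fall into parts. Spots at the scanner ceiling cannot account for all of them, since 9.09% (exact 95% interval 5.72% to 13.6%) had such a saturated spot. The interval treats clones as independent, which they are not. Saturation was counted only at the full ceiling value, so spots with only part of their pixels clipped count as unsaturated here. Whether partly clipped spots add to the calls was not tested. Saturation may account for the calls with a saturated spot. Clone spots at the ceiling numbered 0 on test_in_Cy5 replicate 3, 1 on test_in_Cy5 replicate 4 and 3 on test_in_Cy3 replicate 4. The other arrays had 20 to 37, so full saturation could act on few ratios of these 3 arrays. Of the 22 clones with one, 95.5% were called with Cy3 higher, against 10 of the 100 brightest clones without one. For the saturated calls a signal trend across print blocks is argued against: with loess per block their median effect kept 0.948 of its size. For the other 210 called clones such a trend stays open: loess per block took their median effect to 0.407 of its size, from 0.65 to 0.26 at a residual spread of 0.33 and 0.30, with 15 keeping their call. Without background correction it took that of 735 unsaturated calls to 0.604, with 176 of them keeping their call. In both cases the clones had been selected with loess per array. Over all clones without a saturated spot, the SD of the dye effects went from 0.289 to 0.174 with loess per block. Without background correction that SD went from 0.0635 to 0.0546. Whether the lean of the calls to Cy3 comes from normexp stays open: Cy5 was higher for 17.3% of the 231 calls and for 47.5% without background correction, where calls with Cy5 higher rose from 40 to 359 and those with Cy3 higher from 191 to 397, but it was also higher for 43.0% with median centring and for 42.4% among clones above the blanks, both with normexp.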

How the results depend on the processing

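Intensities divided by 80, the blank filter and the omission of both arrays numbered 4 were chosen after the data were seen. Values are ordered as dye calls, unswapped calls in test_in_Cy5 and test_in_Cy3, agreement r, shares over 1 in single arrays, same-orientation means and swap-corrected ratios, and residual spread, against 231, 22, 0, 0.606, 5.68%, 3.67%, 1.29% and 0.249. The cause of each change was not tested unless stated.

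Without background correction they were 756, 351, 55, 0.821, 0.308%, 0.262%, 0% and 0.0669. Log2 ratios were narrower in this setting, so its shares and spread are not on the scale of the main values. Plain subtraction gave 653, 286, 49, 0.804, 0.308%, 0.262%, 0% and 0.0712. The authors' values gave 447, 321, 14, 0.418, 0.0171%, 0%, 0% and 0.0567. Loess per print block gave 35 dye calls, 0 in test_in_Cy5, an r of 0.416, 2.92% in single arrays, 1.25% in means, 0.541% in swap-corrected ratios and a spread of 0.208. Median centring, which leaves the intensity trend in, gave 2534 dye calls, 428 in test_in_Cy5, an r of 0.772 and 6.20% in means. Intensities divided by 80 gave 60 in test_in_Cy5, 2.06%, 0.775%, 0.0570% and a spread of 0.214. The blank filter, which left 950 clones to test, gave 85, 61, 28, 0.912, 2.32% in single arrays, 2.11% in means, 0% in swap-corrected ratios and a spread of 0.0890. The intensity dependence of 0.68 became 1.17 without background correction and 1.19 with subtraction.

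A log2 limit of 1 left 58 dye calls, ordinary least squares gave 34, and the omission of both arrays numbered 4 gave 59, of which 49 were among the 231 in the same direction, and 0 in test_in_Cy5. Array weights gave 265, the flag filter 180 and division by 80 gave 286 dye calls. The labels give 1 array of each orientation the same numbered source names. The numbers were not taken as pairs. Deviations of clones from the orientation means correlated at -0.018 to 0.162 for the same number and at -0.209 to 0.249 otherwise. These values cannot decide whether a number marks shared samples, because all samples hold the same rat RNA. The control spots, which were reversed on both arrays numbered 4, leave a link by number open. With the number as a replicate block, 150 dye calls and 0 for test over ref were made on 3 residual degrees of freedom, and UI-R-C0-iw-d-08-0-UI and UI-R-C0-gu-e-07-0-UI had adjusted p values of 0.0596 and 0.0651.

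Leaving out 1 array at a time gave 31 to 228 dye calls, 0 to 1 for test over ref (1 without test_in_Cy3 replicate 2), 0 in either unswapped orientation, an r of 0.494 to 0.611, shares of 5.45% to 5.91%, 2.89% to 3.91% and 1.25% to 1.40%, a spread of 0.237 to 0.254 and an intensity dependence of 0.58 to 0.75. Test over ref stayed at 0 calls under each of the other 22 alternatives run. Among them, the log2 limit of 1 could only remove calls, so it tests nothing for test over ref. The 4 named clones kept their sign in every alternative that tested them, and lost their call in 3 to 10 of these alternatives. Aquantile scaling, which leaves within-array ratios as they are, and the local background filter, which removed no clone, moved nothing and test nothing.

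Gene lists, marker detection and their alternatives were not run because no clone has a gene name here, and no scan date or slide was used as a block because none is given in the sources used here. Signal over background limits most clones, as 65.5% never exceeded the 95th percentile of the blanks in both channels.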

Other observations

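Grouping of clones by the library prefix of their identifier was chosen after the data were seen. The share of clones above the blanks on all 8 arrays differed between the 10 prefixes. It was 24.7% of 507 clones of UI-R-A1, 19.6% of 1492 of UI-R-A0 and 19.0% of 357 of UI-R-E0, against 4.09% of 1075 of UI-R-C1 and 1.42% of 564 of UI-R-C2. What tissue each library was made from is not given in the sources used here. No prefix was shifted as a set in its dye effect by limma's camera with a preset correlation of 0.01, at an adjusted p of 0.961 for each prefix, and with an estimated correlation the smallest adjusted p was 0.238, for UI-R-C2. Most of the dye calls over 1 without background correction, 18 of 23, were of clones with a saturated spot.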
